A study of Mus musculus with 2 samples.

How the data were processed

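Small RNA was sequenced from fibro-adipogenic progenitors (FAPs) of mouse skeletal muscle, kept for 24 h in basal medium (BM) or in adipogenic differentiation medium (ADM), with 1 library per medium. Per the labels' protocols, small RNA was taken up with a mirVana kit, libraries were made with the Illumina TruSeq small RNA kit, a gel band of 147 bp was cut out, and sequencing was on a MiSeq. Growth before the switch was in 20% FBS, 10% HS and 5 ng/ml FGF to about 80% confluence, and BM held 10% HS. The composition of ADM is not given in the sources used here.

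Per the file headers, the deposited values came from miRanalyzer, whose version, filters and treatment of reads that map to several places are not given in the sources used here. The mouse build mm10 is named in the submitters' processing notes. The authors expressed each mature miRNA as a percent of reads, and the deposited columns sum to 99.9% in each library. Nearly all reads taken as 100% thus lie in listed miRNAs, and whether other reads of a library were left out is not given. Percents of BM or ADM reads below are shares of the reads taken as 100%, not of all sequenced reads. In the authors' second table each 0 was replaced by the value of 0.5 read, and the authors' ratio column holds the ADM percent divided by the BM percent. The authors' log column is headed ln2, but its deposited values equal the log2 of that ratio. A further deposited column holds the mean percent of both libraries.

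All percent values (100% in each library, tolerance 0.001 of a read) were whole multiples of the smallest value above 0 in their column. That step was taken as 1 read, which gave 755193 reads in BM and 790617 reads in ADM as the denominators. The authors' 0.5-read replacement equals 0.5 of the same step. Reads per miRNA were recovered on this basis, and percent values were also written as RPM, the percent value times 10000. A single read equals 1.32 RPM in BM and 1.26 RPM in ADM, and 3 counts, the floor used for a miRNA listed at 0, equal 3.97 and 3.79 RPM. Reads outside the listed miRNAs came to 679 in BM and 807 in ADM and stay in the denominators.

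The main measure was log2((ADM + 1)/(BM + 1)) in RPM, which understates the difference for miRNAs of low level. A miRNA was called higher or lower in the ADM library when the mean of both libraries was at least 10 RPM and the difference was at least 2-fold. The ratio of percent values was given a 95% exact conditional (Clopper-Pearson) interval from the recovered reads, and shares of a library an exact Clopper-Pearson interval. Folds with an interval are ratios of percent values without the pseudocount. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. With 1 library per medium no p-value was computed.

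The 23 miRNA lists were fixed before the data were examined, as were the size rule, the level minimum and the naming rule. They cover muscle-enriched miRNAs, miRNAs reported to promote or to inhibit adipogenesis, let-7, miR-29, miR-17-92 with its paralogous clusters, the family of miR-15, miR-16, miR-195 and miR-497, the X-linked cluster of miR-322, miR-351, miR-450, miR-503 and miR-542, miR-34, the clusters of miR-199 with miR-214, of miR-143 with miR-145, of miR-23, miR-27 and miR-24, and of miR-221 with miR-222, miR-30, miR-181, the family of miR-10, miR-99, miR-100 and miR-125, the Dlk1-Dio3 imprinted cluster, other imprinted loci, inflammation-induced, haematopoietic and serum, endothelial, epithelial, and neural and glial miRNAs. A list holds all mature arms of its members. The lists overlap, and 16 of the 27 measured members of the promoting list and 15 of the 24 of the inhibiting list also belong to another list. Each median was placed among the medians of 10000 random lists of the same size, matched on deciles of mean level, as a description of these libraries, and lists with fewer than 3 members above the minimum got values only. Random lists draw arms singly, while both arms of a hairpin (Pearson r 0.77 across hairpins) and neighbouring hairpins tend to have similar ratios. Percentiles of lists that hold such arms therefore overstate how unusual the lists are. Median intervals come from 1000 Poisson redraws of the reads. The named miRNAs are those with the 10 highest and 10 lowest ratios among miRNAs of at least 100 RPM, the 10 most abundant, every muscle-enriched miRNA, and of each other list its most abundant members and the member with the largest ratio in either direction. Any miRNA named outside this rule is said to be chosen after its values were seen.

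For hairpins with both arms above the minimum, the log2 ratio of the 5p arm minus that of the 3p arm was taken, with a normal 95% counting interval. Hairpin positions are from GENCODE M21 (GRCm38, the assembly that mm10 names), matched by name for 598 of the 628 rows and 322 of the 337 above the minimum. The rows of 7 entries name 2 miRNAs that share a value.

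Alternatives were pseudocounts of 0.5 and 10, no minimum or a minimum of 100 RPM, thresholds of 1.5-fold and 3-fold, 4 other scalings (trimmed mean of M values, median ratio, upper quartile, and the total without the most abundant miRNA), RPM of the listed reads, the authors' ratio, and the more abundant arm of each hairpin. The trimmed mean of M values (trimming 30% of ratios and 5% of levels) was computed in own code, since the files hold percent values where the design had foreseen a count tool. It lowers log2 ratios by up to 0.11, and the median over all miRNAs goes from -0.02 to -0.13; the other scalings shift it less. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

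The calculation was tested on simulated reads for 628 miRNAs with the levels and depths of this BM and ADM comparison. Reads were independent Poisson draws without variation between cultures or library preparations. The rates below thus cover counting error only and are not false-call rates for a comparison of single libraries. After the differences were set, all simulated ADM levels were rescaled to the total of the BM levels. True ratios thus differ from the set ones by a common factor, also for miRNAs given no difference. Of the miRNAs given a 4-fold difference and above the minimum, 100% were called, against 85.9% at 2.5-fold and 1.77% of those given none. The interval held the true ratio for 98.1%, 96.9% and 95.6% of them. Lists were simulated among the 342 miRNAs above the minimum. A simulated list of 12 miRNAs, lowered 2-fold in their computed ratios, had percentile 0, and 6% of 100 lists without a difference fell outside the central 95%. Both outcomes were nearly fixed in advance. The other simulated ratios spread by counting error only, and the lists without a difference were drawn singly, as the random lists are. These values check the calculation and give no rate for lists of linked arms.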

Results

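Mature miRNAs were measured in cultured FAPs, mesenchymal progenitors of skeletal muscle that can form adipocytes and fibroblasts. The cells had been sorted as Sca1-positive cells from muscle of wild-type C57Bl/6 mice. After growth, 1 culture sample was kept in BM and 1 in ADM for 24 h, and each gave 1 library. The comparison asks how the miRNA profile of FAPs differs early after exposure to adipogenic medium. The denominators were 755193 reads in BM and 790617 reads in ADM. Of 628 listed miRNAs, 570 were above 0 in BM and 562 in ADM. No replicate check was possible, so each difference is between these libraries and not shown to belong to the media.

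miR-22-3p was the most abundant miRNA in both libraries, with 12.2% of reads in BM (95% interval 12.2 to 12.3%) and 13.2% in ADM (13.1 to 13.3%). Its hairpin lies on chromosome 11 at 75463716-75463810 (GRCm38), in an exon of Mir22hg. miR-21a-5p, from an exon of Vmp1 on chromosome 11 at 86584067-86584158, followed with 9.72% and 13.0%. The 10 most abundant miRNAs of each library held 56.6% of BM reads (56.4 to 56.7%) and 59.9% of ADM reads (59.8 to 60.0%). The 10 most abundant by the mean of both libraries also took in miR-26a-5p (6.66% in BM and 4.09% in ADM), miR-99b-5p (5.68% and 2.999%), miR-148a-3p (3.40% and 5.27%), let-7f-5p (3.73% and 4.79%), miR-143-3p (2.86% and 5.35%), miR-92a-3p (3.87% and 3.63%), miR-10b-5p (3.72% and 3.47%) and let-7c-5p (2.67% and 4.04%).

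The ADM library held far more miR-138, miR-155-5p and miR-146b-5p than the BM library, and less miR-133a-3p and less of most of the Dlk1-Dio3 miRNA cluster. Among 337 miRNAs above the level minimum, 36 were at least 2-fold higher and 69 at least 2-fold lower in the ADM library. The counting interval excluded a ratio of 1 for 35 of the higher and 66 of the lower miRNAs. Members of the Dlk1-Dio3 cluster made up 44 of the 69 lower miRNAs (63.8%). Without that cluster, the counts were 36 higher and 25 lower.

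**Figure D1:**
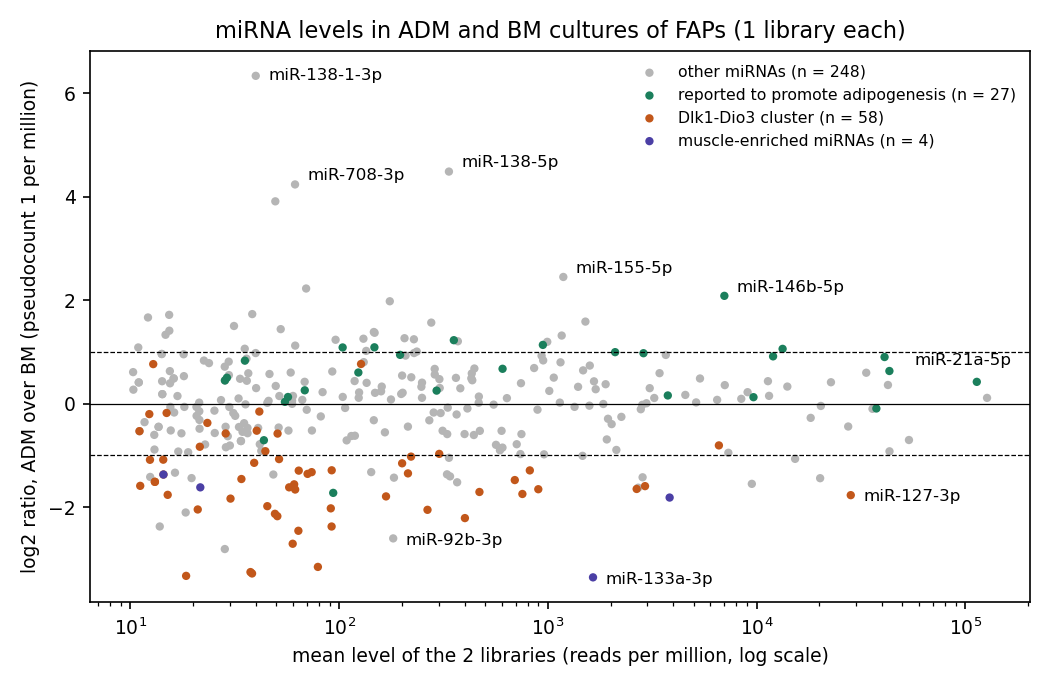
Each point is a miRNA above the level minimum, with its mean level in RPM (log scale) on the x axis and its log2 ratio of the ADM to the BM library on the y axis; dashed lines mark 2-fold. miR-138-5p (4.48) lies far above and miR-133a-3p (-3.36) far below the other abundant miRNAs, and miR-138-1-3p, listed at 0 in BM, is placed by its pseudocount.

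The highest ratio among miRNAs of at least 100 RPM belonged to miR-138-5p, with 21 reads in BM and 509 in ADM, a 23.2-fold difference (95% counting interval 14.98 to 37.7; log2 ratio 4.48). This miRNA has hairpins on chromosome 9 at 122682876-122682974 and on chromosome 8 at 94324311-94324381, the latter in an exon of the lincRNA C78859. The opposite arm of the chromosome 9 hairpin, miR-138-1-3p, had 0 reads in BM and 63 in ADM and was at least 20.1-fold higher against the floor of 3 counts, which leaves out counting error in the ADM reads; the exact counting interval of its ratio starts at 15.8. miR-155-5p, a miRNA induced in activated immune cells, was 5.47-fold higher (4.81 to 6.24), with 277 and 1586 reads; its hairpin lies in an exon of Mir155hg on chromosome 16 at 84714140-84714204. miR-146b-5p, also on the inflammation-induced list, was 4.24-fold higher (4.04 to 4.45), with 2022 and 8973 reads, and lies in an intron of Mfsd13a on chromosome 19 at 46342762-46342870. miR-582-3p, from an intron of Pde4d on chromosome 13 at 109324744-109324824, was 3.98-fold higher (2.94 to 5.48). miR-192-5p and miR-193a-3p were 3.004-fold (2.73 to 3.31) and 2.97-fold (2.38 to 3.74) higher. The remaining 4 of the 10 highest were miR-126-5p (log2 ratio 1.38), miR-106b-5p (1.37), miR-93-5p (1.32) and miR-20a-5p (1.26).

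At the other end, miR-133a-3p, a regulator of muscle differentiation, was 10.3-fold lower in ADM (8.97 to 11.8), with 2266 reads in BM and 231 in ADM. Its hairpins lie in an intron of Mir133a-1hg on chromosome 18 at 10782909-10782976 and between genes on chromosome 2 at 180398379-180398482. miR-92b-3p, from chromosome 3 at 89227116-89227198, was 6.18-fold lower (4.40 to 8.87), with 236 and 40 reads. The row shared by miR-486-5p and miR-3107-5p was 3.52-fold lower (3.31 to 3.74). The other 7 of the 10 lowest were Dlk1-Dio3 members: miR-540-3p (4.66-fold lower, 3.79 to 5.77), miR-409-5p (4.17-fold, 3.26 to 5.39), miR-337-5p (log2 ratio -1.79), miR-127-3p (-1.77), miR-434-5p (-1.74), miR-381-3p (-1.71) and miR-409-3p (-1.65).

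The Dlk1-Dio3 cluster is an imprinted domain whose miRNAs are expressed from the maternal chromosome. Of its 80 listed arms, 58 were above the minimum; 44 of these were at least 2-fold lower in ADM, 0 were at least 2-fold higher and 14 were neither. The median log2 ratio was -1.49 (counting interval -1.62 to -1.34), below the medians of all 10000 matched random lists. Those lists draw arms singly, while the cluster's arms share a region and are not independent. With a pseudocount of 10 RPM 35 arms were lower and the median was -1.17, outside the counting interval. With the more abundant arm only, 31 of 42 were lower (median -1.35), and with a minimum of 100 RPM 14 of 17 (-1.59). Together the 58 arms took 7.12% of BM reads and 2.41% of ADM reads, a 2.95-fold difference; the muscle-enriched miR-133a-3p was lower in the same library by 10.3-fold. miR-127-3p, on the strand opposite to Rtl1 at 109592846-109592915, alone had 4.37% of BM reads and 1.28% of ADM reads and was 3.41-fold lower (3.33 to 3.48). miR-411-5p (log2 ratio -1.59) and miR-434-3p (-1.65) were also lower, miR-541-5p had a ratio of -0.81, and the lowest ratio of the list was that of miR-665-3p (-3.33), with 26 and 2 reads. Ratios were below 0 for 56 of the 58 arms; the exceptions, named after their values were seen, were miR-494-3p (0.77) and miR-337-3p (0.76).

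Hairpins of these arms span chromosome 12 from 109571990 to 109743795, and lower arms occurred along the whole span. Of 15 arms encoded before the noncoding gene Rian, 13 were lower with a median of -1.65; of 41 arms encoded after it, 29 were lower with a median of -1.46. Both arms from within Rian were lower. Of the other imprinted loci, only miR-335, encoded in an intron of the imprinted gene Mest on chromosome 6 at 30741299-30741396, had members above the minimum. miR-335-5p had 53 reads in BM and 21 in ADM (log2 ratio -1.37) and miR-335-3p had 38 and 5 (-2.81).

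**Figure D2:**
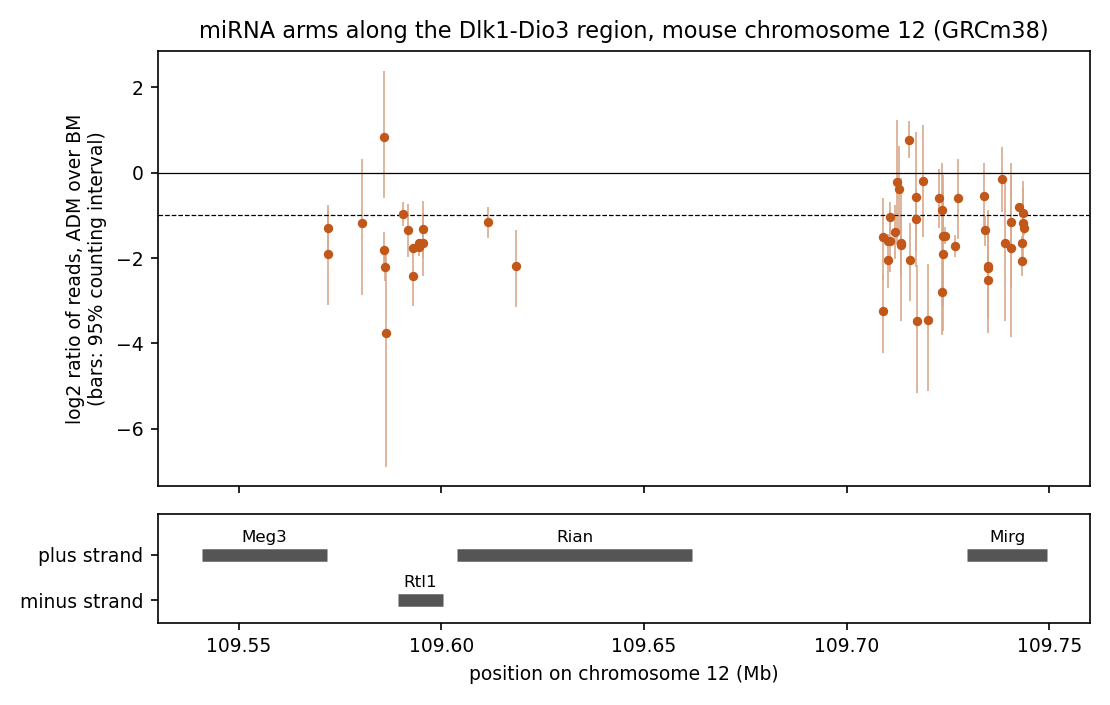
Points are the 58 miRNA arms of the Dlk1-Dio3 region above the level minimum, by position on chromosome 12 (Mb) and log2 ratio of percent of reads, ADM over BM; bars are 95% counting intervals and the lower panel shows genes on each strand. Most arms lie below the dashed line at a 2-fold lower level, before and after Rian alike.

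Muscle-enriched miRNAs were lower in ADM in all 4 of the measured members above the minimum (median log2 ratio -1.72, percentile 0.46). With a minimum of 100 RPM 2 members were left, too few for a percentile, with a median of -2.58. Besides miR-133a-3p and the miR-486-5p row, these were miR-133b-3p, with 25 and 8 reads, and miR-486-3p, with 16 and 6 reads (log2 ratio -1.37, and -0.83 with a pseudocount of 10 RPM). Members below the minimum were miR-206-3p with 8 and 1 reads, miR-1a-3p with 4 and 2, miR-133a-5p with 7 and 1, miR-133b-5p with 5 and 1, miR-208b-3p with 5 and 3 and miR-1b-3p with 0 and 1, and were not compared.

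miRNAs reported to promote adipogenesis were higher in ADM as a group, with a median log2 ratio of 0.63 (percentile 100 among the 10000 random lists). Of 27 measured members, 6 were at least 2-fold higher, 1 was lower and 20 were neither; the higher members numbered 3 with the trimmed mean of M values and 8 with median ratio scaling. miR-146b-5p led the list. miR-143-3p had a log2 ratio of 0.90, miR-148a-3p 0.63 and miR-21a-5p 0.42, while miR-92a-3p had -0.09. The member lower in ADM, named after its value was seen, was miR-204-5p, with 109 and 34 reads (-1.72).

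Among 24 measured miRNAs reported to inhibit adipogenesis, 5 were higher, 4 lower and 15 neither, and the median (-0.11, percentile 34.4) and the mean (0.42) differed in sign. The median was 0.25 without a level minimum, with 11 higher and 5 lower, and 0.01 with the more abundant arm only, with 5 higher and 1 lower. The reported median stays the same with miR-138-1-3p at its bound. The higher members were both miR-138 arms, miR-155-5p, miR-193a-3p and miR-93-5p, and the lower ones miR-222-3p, miR-221-5p, miR-222-5p and miR-369-3p, the last named after its value was seen. With a pseudocount of 10 RPM 2 were lower, and miR-222-5p had -0.96. Of the 4 most abundant members, miR-222-3p was lower (-1.42), while miR-27b-3p (-0.27), miR-221-3p (-0.11) and miR-130a-3p (-0.40) were not 2-fold apart.

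The proliferation-associated miR-17-92 group and its paralogous clusters were higher in ADM by the median of their members, 0.93 (percentile 99.92). Of 15 members, 6 were at least 2-fold higher (4 with the trimmed mean of M values), 0 lower and 9 neither. Their summed share hardly differed, with 4.37% of BM reads and 4.50% of ADM reads. miR-93-5p was 2.49-fold (2.25 to 2.77) and miR-25-5p 2.77-fold (1.67 to 4.80) higher, and miR-19b-3p had a log2 ratio of 0.93 and miR-25-3p 0.59. The most abundant member, miR-92a-3p, had 3.87% of BM reads and 3.63% of ADM reads.

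The cluster of miR-221 and miR-222 was lower in 3 of 4 arms (median -1.43, percentile 1.69). With the more abundant arm of each hairpin only, 2 arms were left with a median of -0.77, and with a minimum of 100 RPM the median of the 3 arms left lay within the central 95% of random lists. miR-222-3p was 2.68-fold lower (2.51 to 2.87), and miR-221-3p, the other abundant arm, had 2185 and 2123 reads. The family of miR-10, miR-99, miR-100 and miR-125 was at least 2-fold lower in 3 of 12 members and less than 2-fold apart in the other 9, with a median of -0.71 (percentile 1.94). Its members took 17.2% of BM reads and 10.3% of ADM reads. miR-100-5p was 2.93-fold lower (2.82 to 3.04), miR-125b-5p 2.71-fold (2.65 to 2.78) and miR-125a-5p 2.09-fold (2.04 to 2.15). miR-99b-5p had a log2 ratio of -0.92, or -1.03 with the trimmed mean of M values, and miR-10b-5p -0.10.

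For most other families the median lay within the central 95% of random lists. let-7 had 1 of 17 members higher, miR-98-5p (log2 ratio 1.20), and a median of 0.36 (percentile 94.1); let-7i-5p had -0.04. miR-30 had 4 of 11 higher, or 2 with the trimmed mean of M values, and a median of 0.40 (91.5). Among these, miR-30b-3p had 5 and 19 reads (1.72) and miR-30a-5p a ratio of 1.06, or 0.95 with the trimmed mean of M values; miR-30c-5p was 1.99-fold apart and miR-30d-5p had 0.13. The cluster of miR-143 and miR-145 had 0 of 4 at least 2-fold apart and a median of 0.76 (97.0), with miR-145a-5p at 0.69. The X-linked cluster of miR-322, miR-351, miR-450, miR-503 and miR-542 had 1 of 6 lower, miR-351-5p (3.08-fold, 2.87 to 3.31), or 2 with the trimmed mean of M values, and a median of -0.65 (12.6), which falls outside the central 95% when random lists are drawn without Dlk1-Dio3 members; miR-322-5p had -0.59. The cluster of miR-199 and miR-214 had 1 of 5 lower, miR-199b-5p (-1.05), or 2 with the trimmed mean of M values, and a median of -0.59 (9.30); the row shared by miR-199a-3p and miR-199b-3p had -0.44, miR-199a-5p -0.95 (-1.05 with the trimmed mean of M values) and miR-214-3p -0.29.

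Within the family of miR-15, miR-16, miR-195 and miR-497, 2 of 7 members were lower (1 with a pseudocount of 10 RPM), among them miR-497-5p (-1.43). The median was -0.06 (percentile 45.6), but 0.31 without a level minimum and 0.33 with a minimum of 100 RPM or the more abundant arm only, while the abundant miR-16-5p had 0.33. The clusters of miR-23, miR-27 and miR-24 had 0 of 8 at least 2-fold apart (median 0.25, percentile 81.3), with miR-23b-3p at 0.84 and miR-24-3p at 0.74. The matrix-targeting miR-29 family had 0 of 4 apart, with a median of 0.09 that is -0.02 with the trimmed mean of M values (percentile 55.3). The p53-induced miR-34 family had 0 of 5 apart (median 0.33, percentile 68.5), with miR-34a-5p at 0.80, and miR-34c-5p at 0.09, or -0.01 with the trimmed mean of M values. miR-181 had 0 of 6 apart (median -0.08, percentile 38.8), with miR-181a-5p at 0.15 and miR-181c-3p at -0.84. The inflammation-induced list had 2 of 8 higher, miR-155-5p and miR-146b-5p, and 0 lower (median 0.36, percentile 87.9), and miR-132-3p had 0.11.

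Of the markers of other cell types, the endothelial miR-126-5p was 2.63-fold higher (1.95 to 3.59), with 61 and 168 reads, while its opposite arm miR-126-3p had 27 and 35 reads (log2 ratio 0.30). The epithelial list had 0 of 3 members at least 2-fold apart (median -0.04, percentile 44.7, or 0.04 for the 2 members left with a minimum of 100 RPM), with 1211 and 1234 reads of miR-182-5p, 90 and 102 of miR-183-5p, and 17 and 15 of miR-203-3p. Of 3 neural and glial members, miR-128-3p was lower (2.58-fold, 2.13 to 3.16), miR-218-5p had a ratio of 0.56 and miR-218-1-3p -0.45 (median -0.45, percentile 27.4). Both haematopoietic and serum miRNAs listed above 0 were below the minimum, miR-150-5p with 1 and 3 reads and miR-451a with 0 and 1.

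**Figure D3:**
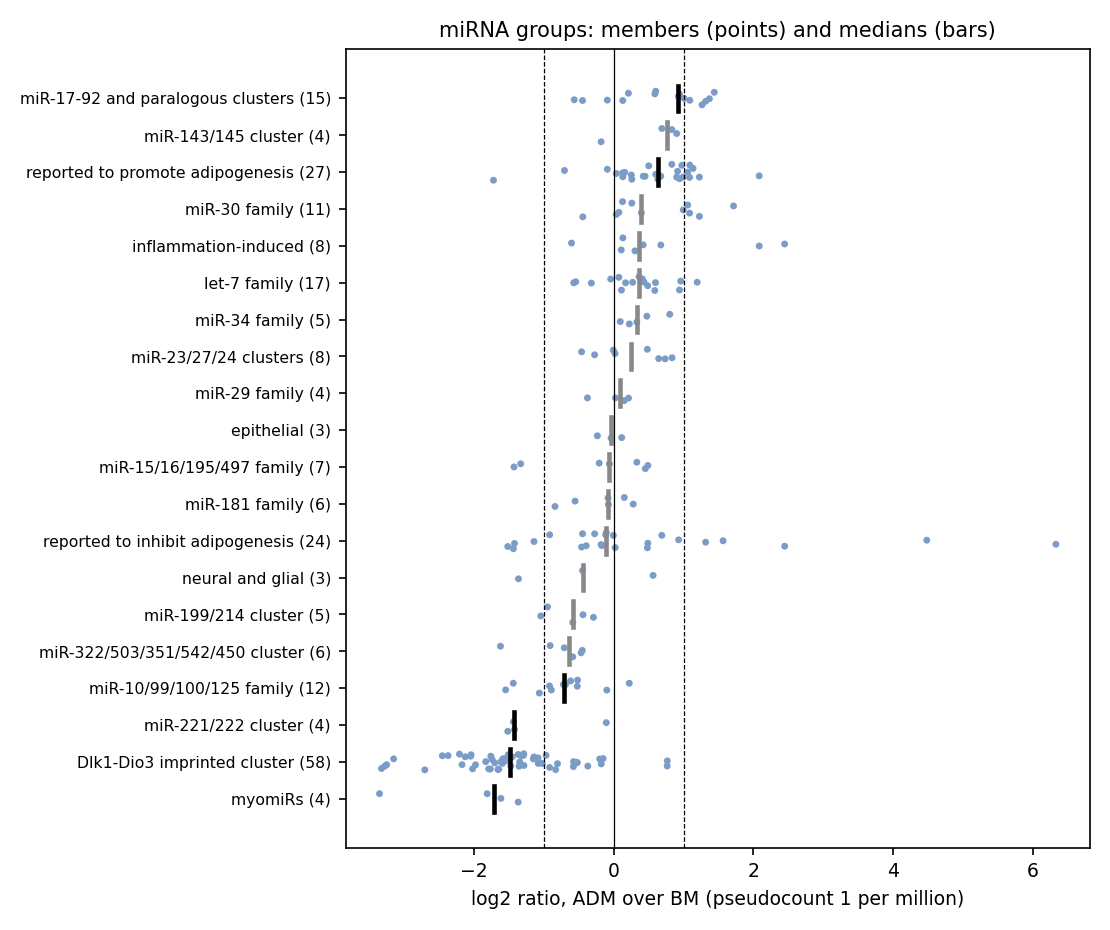
Points are the members above the level minimum of the 20 miRNA lists with at least 3 such members (number in brackets), by log2 ratio of the ADM to the BM library; bars are medians, black where the median lies outside the central 95% of matched random lists. The black bars are miR-17-92 (0.93) and the promoting list (0.63) on the higher side, and the family of miR-10, miR-99, miR-100 and miR-125 (-0.71), the cluster of miR-221 and miR-222 (-1.43), Dlk1-Dio3 (-1.49) and the muscle-enriched list (-1.72) on the lower side.

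Both arms of a hairpin come from the same precursor, so their ratio does not depend on the scaling of a library. Of 89 hairpins with both arms above the minimum, 66 had arms on the same side of 0, and the median absolute difference between arms was 0.49 on the log2 scale. In 14 hairpins the arms differed by at least 1, and in 10 of these the counting interval excluded 0. The 5p arm was the relatively higher one in ADM in 11 of the 14. The largest differences beyond counting error, named after their values were seen, were those of miR-337 (-2.56), miR-376b (1.87), miR-93 (1.76) and miR-379 (1.70). They rest on few reads of at least 1 arm. miR-93-3p, with 12 reads in BM and 9 in ADM (-0.45), did not go the way of miR-93-5p. For miR-221 the 5p arm was lower relative to the 3p arm by a difference of -1.41 (-1.69 to -1.13). For miR-106b the 5p arm was relatively higher (1.16, 0.60 to 1.72), with 62 reads of 5p against 104 of 3p in BM and 169 against 126 in ADM. The major arm was another in ADM than in BM for 6 hairpins, in 2 of which the arm difference exceeded counting error.

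In the authors' deposited table, 15 miRNAs had a ratio above 5 and 25 a ratio below 0.2. Of these, 5 and 11 had a mean of at least 10 RPM. The authors' deposited table gives a ratio of 23.2 for miR-138-5p, 5.47 for miR-155-5p and 120 for miR-138-1-3p, the last resting on the replacement of 0 by 0.5 read.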

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

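Alternatives chosen after the data were seen were leaving out the Dlk1-Dio3 list, random lists without its members, and a counting interval that excludes 1. Without Dlk1-Dio3 members the count of miRNAs at least 2-fold apart was 61, with 25 lower. Without a level minimum it was 289 (131 higher, 158 lower), and with a minimum of 100 RPM 50 (21 and 29). A 1.5-fold threshold gave 179 (75 and 104) and a 3-fold threshold 47 (12 and 35), by construction. The share of higher among these was 34.3% as reported, 45.3% without a minimum and 59.0% without Dlk1-Dio3 members, where the majority of calls was higher instead of lower. Hairpins with arms at least 1 log2 apart numbered 9 with a pseudocount of 10, 2 with a minimum of 100 and 55 without a minimum, where low counts set many ratios. The other 42 of 59 alternatives to these results stayed within their limits, a factor of 1.5 in either direction for counts and the counting interval for library shares. These limits are wide, and several alternatives could hardly differ. A pseudocount of 0.5 and RPM of the listed reads gave the same 36 higher and 69 lower miRNAs. Of the called ratios of named miRNAs and the list medians outside the central 95%, 0 changed sign. For the named miRNAs this was fixed in advance. A pseudocount cannot turn a sign, and no scaling moved a log2 ratio by more than 0.11. List medians outside the central 95% numbered 6 under every pseudocount and scaling. For the scalings this was nearly fixed in advance, since a scaling moves all ratios almost alike and leaves their ranks. The number was 5 with the more abundant arm only, where 2 arms of miR-221 and miR-222 were left. With a minimum of 100 it was 5, where the miR-221 and miR-222 cluster and the muscle-enriched list dropped out and miR-30 was added. It was 7 without a minimum or with random lists free of Dlk1-Dio3. Of 219 alternative list medians 14 moved beyond counting error, and of 742 alternative ratios of named miRNAs 68 did. Depth limits miRNAs near 10 RPM, where the reads are few. No paired analysis was possible because each medium had 1 library, and for the same reason no library was left out.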

Other observations

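The tests of GC content and of neighbouring hairpins were set before their results were seen; the tests of scaling, counting error, overamplification and myogenic cells were chosen after. Outside the naming rule, and chosen after their values were seen, a few further miRNAs stood out in both arms. miR-708-3p had 4 reads in BM and 93 in ADM, 22.2-fold higher (8.39 to 83.2), and miR-708-5p had 4 and 74, 17.7-fold higher (6.62 to 66.6). miR-345-3p was 4.83-fold (2.89 to 8.51) and miR-345-5p 3.45-fold (1.84 to 6.96) higher. On the lower side, miR-1247-5p had 18 reads in BM and 3 in ADM (log2 ratio -2.37), and miR-1247-3p had 23 and 5 (-2.10). Both arms, encoded near Dio3 but not in the fixed list, went the same way as most Dlk1-Dio3 members, on few reads.

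Hairpins close to each other tended to have similar ratios. Outside the Dlk1-Dio3 region, 42 pairs of hairpins within 10 kb had a mean absolute difference of 0.64 in log2 ratio, against a median of 1.02 in 10000 shuffles of 162 hairpins (percentile 0.26), and 31 pairs had the same sign. Shared transcription of neighbouring hairpins may contribute to this, though the pairs overlap and are not independent. Exceptions, named after their values were seen, included miR-99b-5p (-0.92) and miR-125a-5p (-1.07) against their neighbour let-7e-5p (0.11), and miR-222-3p (-1.42) against miR-221-3p (-0.11).

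Dlk1-Dio3 miRNAs were lower in the ADM library across the region. Scaling set by a few abundant miRNAs is argued against, since the highest list median under 4 other scalings was -1.46. GC content was taken over the side of the hairpin that holds an arm, not over the mature miRNA. Measured so, a trend like that of the other miRNAs is argued against, since it was small and ran the other way. Their log2 ratio fell by 0.02 per percentage point of GC, and median GC was 46.5% in the list and 50.4% in the others. After its removal the list median was -1.73, against -1.49 before. The other miRNAs moved too, by a median of 0.15 in either direction, so this move is not a measure of GC content alone. The GC trend was weak (Pearson r -0.17), so this test could hardly have accounted for the lower list, and GC content of the mature miRNAs was not tested. Fewer myogenic cells in the ADM culture could account for part of it: the median ratio of the list, 0.342, lies above the interval of miR-133a-3p (0.0847 to 0.112), so for a member at that median 72.9% of its BM reads would have to come from cells lost as fully as miR-133a-3p. Intervals of 46 of the 58 members lie above that upper bound. The reckoning also takes miR-133a-3p as the mark of such cells, while miR-206-3p and miR-1a-3p had only 8 and 4 reads in BM. No profile of such cells was used here to say which share they hold, so this explanation stays open. A response of the locus to the medium stays open too and was not tested, with 1 library per medium.

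miR-133a-3p and the other 3 muscle-enriched miRNAs above the minimum were lower in ADM. For miR-133a-3p and the miR-486-5p row, counting error is argued against by the smaller lower bound of their folds, 3.31. The lower bounds of miR-133b-3p and miR-486-3p were 1.43 and 1.04, so for these counting error leaves open a difference below 2-fold. If fewer myogenic cells, which a Sca1 sort would largely remove, were the cause, miR-1a-3p and miR-206-3p could be expected beside miR-133a-3p. That expectation bears only on myogenic cells that hold both in abundance, and their levels in such cells were not measured here. In BM both together gave 0.0053 reads per read of miR-133a-3p, which had 566 times the reads of miR-1a-3p. Unequal capture of single miRNAs by ligation and the lack of a muscle library prepared alike keep fewer myogenic cells open as an explanation. A response to the medium was not tested.

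miR-138 and miR-708 were higher in ADM in all 4 arms. Counting error is argued against for miR-138-5p by its lower bound of 14.98. Overamplified single molecules stay open: the smallest lower bound over the arms, 6.62, takes reads as independent molecules, and miR-708 was picked because both its arms stood out. A response to the adipogenic medium and a difference between these cultures for another reason stay open, and neither was tested with 1 library per medium.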
